A study of Nothobranchius furzeri with 10 samples.

How the data were processed

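RNA sequencing was done on the livers of 10 male Nothobranchius furzeri, the turquoise killifish, a short-lived fish used in ageing research. All fish were 10 weeks old and of the same transgenic strain, labelled line 4010; Tg(mylz2:egfp,tfam). The perturbation label gave 5 swim-tunnel livers, called exercised here, and 5 livers of fish without exercise, called control. Each library carries its own number in the labels, and these numbers are not shared between the groups, so the labels pair no samples. The numbers run in a separate block for each group. If they follow an order of collection or handling, which is not stated, that order cannot be told apart from group. Replicates were numbered 1 to 5 within a group in accession order. No label names a sequencing batch, a day or a tank, and nothing states that the 10 samples came from separate rearing units, so p-values measure only the spread between these samples.

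Libraries were made from total RNA with the TruSeq RNA kit version 2, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build, the annotation, the strand setting and the read layout are not given in the sources used here. The deposited counts are whole numbers of reads per gene for 26739 genes in 10 columns, not normalized, and every row names a gene. The deposited RPKM table holds the same genes and libraries; per its name, a value is the reads per kilobase of gene, scaled to the number of counted reads. The RPKM values were compared cell by cell with the counts. They equal the count divided by a gene length and a library total, but the total was not that of the library in the column for most cells, as described in the results, so the counts were used for every main result.

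The identifiers in the tables were looked up in the reference table of the species, NfurGRZ-RIMD1, and 0 of 26739 were found in it. The files do not pair identifiers with gene names either. The 43 gene lists fixed before the data were examined, among them glucose, glycogen and lipid metabolism, stress responses and markers of other cell types, could therefore not be matched, and 0 were tested. The genes of the transgene construct were not analysed here for the same reason. The rule fixed for genes to name asked for genes with a symbol, of which there were none. In its place, the 2 identifiers with the smallest p in each direction are printed, and other genes are described by their number, size of change and abundance. Contamination by another tissue could not be examined without gene names.

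Genes were kept by edgeR's filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), and 15621 genes remained, holding 99.91% of all counts. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, a design of intercept and group, and all 10 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are exercised over control on the log2 scale, with the standard error taken from the fitted change and its F statistic. CPM values are counts scaled to library size with TMM factors. Single values per library were compared by exact permutation over all 252 assignments of 5 of the 10 libraries, whose smallest two-sided p is 0.00794, with adjustment over the 10 measures tested. Principal components were computed on log2 CPM with a prior count of 2, and similarity of libraries as Spearman's correlation over the tested genes.

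The alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 5 libraries, robust dispersions, DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, limma on log2 of the deposited RPKM with pseudocounts of 1 and 0.1, a threshold of 0.10, and each library left out in turn. Added after the data were seen were library totals without factors, RPKM rebuilt with each library's own total, removal of each library's trend on gene length, factors computed without the 100 most abundant genes, and leaving out the most dissimilar library of each group. Gene lengths were recovered from the ratio of counts to RPKM for 22159 genes.

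Library totals lay between 26850938 and 40089247 counts, and the common biological coefficient of variation between livers of a group was 38.29%. The tests were tried on simulated data for the exercised and control comparison, with 199 changed genes among the 15517 that entered the step. Means and library sizes were those of the real data, and dispersions were those edgeR estimated from it. Each gene was drawn independently, so genes that vary together were not simulated. The numbers of false calls hold only for such data. The main test called 80% of the 65 genes changed 4-fold, 14.9% of the 67 changed 2-fold and 0% of the 67 changed 1.5-fold, with 0 false calls. A gene that was not called is therefore not shown to be unchanged. These shares were found with 199 changed genes. The adjusted p depends on how many genes change, and the main test called 514 genes in the real data against 62 here. The shares may therefore differ in the real comparison. No library was a copy of another: the lowest chi-square per degree of freedom over the 45 pairs of libraries was 60.97.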

Results

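The livers of 5 killifish that swam in a swim tunnel were compared with the livers of 5 fish without exercise, to ask how physical exercise changed liver gene expression. The exercised libraries held 31773232 ± 5195823 counts (SD, n = 5) and the control libraries 31593206 ± 2997117 (SD, n = 5), a difference within the spread (exact permutation p = 0.96, two-sided). Counts were found for 22159 of the 26739 genes in the table. Thinned to the depth of the smallest library, 26850938 counts, exercised livers showed 19678 ± 288 genes and control livers 19819 ± 377 (SD, n = 5 each; exact permutation p = 0.548). The 10 most abundant genes took 14.8 ± 3.49% of counts in exercised livers and 17.19 ± 2.85% in control livers (SD, n = 5 each; exact permutation p = 0.294; the difference of -2.39 percentage points ranged from -3.86 to -1.56 with 1 library left out), and the 100 most abundant took 44.64 ± 4.71% and 48.8 ± 4.58% (exact permutation p = 0.214). The tables name genes only by identifiers that could not be paired with gene symbols.

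Exercise was accompanied by higher levels of 318 genes and lower levels of 196 genes, 3.29% of the 15621 tested (edgeR's quasi-likelihood test, adjusted p under 0.05). The genes that rose did so by a median of 2.02-fold, with quartiles of 0.79 and 1.32 on the log2 scale. The genes that fell were a median of 2.27-fold higher in control livers, with quartiles of -1.54 and -0.85 on the log2 scale. These sizes are of called genes only, and the threshold favours large changes. Over all tested genes the median absolute change was 0.298 on the log2 scale. At least a doubling was seen for 163 of the genes that rose, and 124 of those that fell dropped by as much. Changes of at least 4-fold were found for 24 genes that rose and 18 that fell, and the called changes reached 5.59 and -3.44 on the log2 scale. An unadjusted p under 0.05 was found for 3365 genes, against 781.1 expected on average if no gene changed. Genes that vary together can move a single chance result far from that average, and its spread was not examined. In 270 of the 318 higher genes every exercised liver lay above every control liver, and in 165 of the 196 lower genes every exercised liver lay below. Such separation was found in 931 of all tested genes, or 5.96%, where chance gives 0.794% on average.

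Of the called genes 61.9% rose. Scaled to library totals alone the split was 465 higher and 90 lower, or 83.8% higher, because that scaling places the median of all tested genes at 0.15 on the log2 scale, against -0.02 with TMM factors. Upper-quartile factors moved the split the other way, to 257 higher and 229 lower, or 52.9% higher. The counts depended on single libraries: without control replicate 2 there were 51 higher and 28 lower genes, and without control replicate 4 there were 493 and 330. Without control replicate 5 the split was 162 and 137, or 54.2% higher. A loss of calls did not mark an unusual liver: control replicate 2 had the highest mean correlation with the other livers, 0.949. Its sample weight in limma-voom was also the highest, 2.57, and that of control replicate 4 was low, 0.594. Control replicates 3 and 5, with weights of 0.813 and 0.545, went the other way, as calls were lost without them. Why the counts moved was not tested. All 514 called genes kept their direction in each of these fits, and in each of the other alternatives tried in which they were tested. The 514 were chosen on the same libraries, so their kept direction is largely set by that choice.

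**Figure D1:**
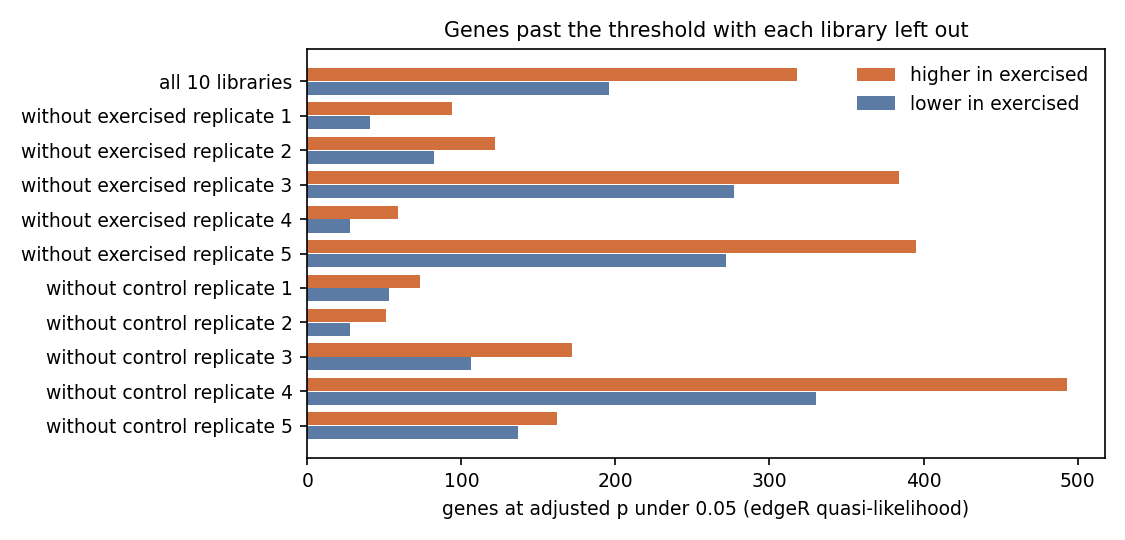
Number of genes past an adjusted p of 0.05 (x axis) with all 10 libraries and with each library left out (y axis); upper bars are genes higher and lower bars genes lower in exercised livers. The counts run from 51 higher and 28 lower without control replicate 2 to 493 and 330 without control replicate 4, against 318 and 196 with all libraries.

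The genes with the smallest p in each direction were separated completely between the groups. Nfu_g_1_005339 stood at 103.2 ± 13.44 CPM in exercised livers and 41.44 ± 5.638 CPM in control livers (SD, n = 5 each), a log2 change of 1.32 ± 0.147 (SE; edgeR adjusted p = 0.0104). Nfu_g_1_000441 was 4.71-fold higher, at 135.1 ± 33.38 against 28.69 ± 10.19 CPM (SD, n = 5 each; edgeR adjusted p = 0.0104). Among the genes that fell, Nfu_g_1_010862 stood at 4.473 ± 1.71 CPM in exercised and 23.74 ± 6.184 CPM in control livers (SD, n = 5 each), 5.33-fold higher in control (edgeR adjusted p = 0.0104). Nfu_g_1_016078 stood at 9.852 ± 4.08 and 51.02 ± 13.45 CPM (SD, n = 5 each), 5.18-fold higher in control livers (edgeR adjusted p = 0.0104). Each of these 4 genes kept its call whichever single library was left out, though they were chosen for their small p on these same libraries. With 2 libraries left out, exercised replicate 2 and control replicate 5, the directions stayed and the adjusted p rose to between 0.0544 and 0.0557.

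**Figure D2:**
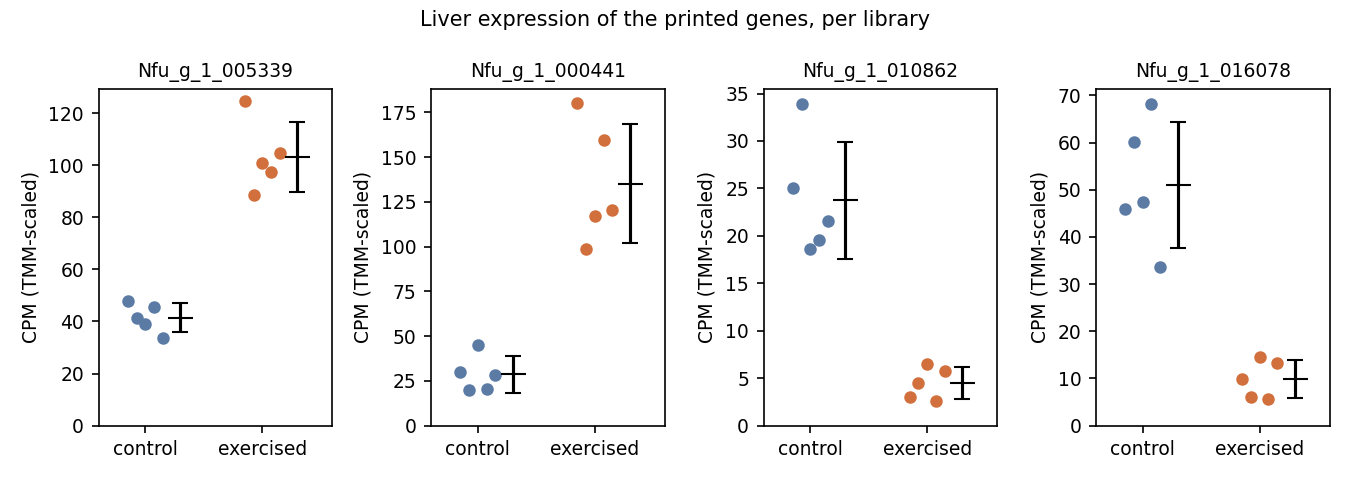
CPM after TMM scaling (y axis) of the 2 genes with the smallest p in each direction, in 5 control and 5 exercised livers; points are libraries, and the bar beside them is the mean with its SD. Nfu_g_1_005339 ranged from 88.4 to 124.7 CPM in exercised and from 33.51 to 47.82 CPM in control livers, and the groups do not overlap in any of the panels.

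Changed genes were found at all levels of abundance. Among the 169 called genes that averaged under 10 CPM, 83 rose and 86 fell. Among the 345 at 10 CPM or more, 235 rose and 110 fell, a share of 68.1% against 49.1% (Fisher's exact test, p = 4.56e-05; genes are not independent replicates). A division at 100 CPM showed no such difference (odds ratio 1.15, Fisher's exact test, p = 0.73). Both divisions were chosen after the data were seen and were made with TMM factors only. The share of all called genes that rose was 52.9% with upper-quartile factors and 83.8% with library totals. Whether the split at 10 CPM holds under those scalings was not tested. The median change of all tested genes moved in the same order as the split at 10 CPM, from -0.215 on the log2 scale under 1 CPM and -0.04 between 1 and 10 CPM to 0.065 between 10 and 100 CPM. It was -0.115 between 100 and 1000 CPM. The moderately expressed genes, between 10 and 100 CPM, held most of the calls, with 211 higher and 97 lower of 5778 tested, or 5.33%. Between 100 and 1000 CPM, 21 genes rose and 12 fell of 742 tested. Of the 192 most abundant genes, at 1000 CPM or more, 3 rose and 1 fell, and the median change of this class was -0.28 on the log2 scale. Under 1 CPM, 9 genes rose and 14 fell of 2018 tested, by medians of 2.12 and -1.65 on the log2 scale. These medians are also of called genes only.

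Whole profiles were on average more alike within a group than between groups, but not for every liver. Spearman's correlation averaged 0.952 among exercised livers, 0.943 among control livers and 0.935 between the groups (exact permutation of the excess within groups, one-sided p = 0.0159). Control replicate 3 correlated at 0.946 with the other control livers and 0.948 with the exercised livers, and control replicate 4 at 0.939 and 0.943; the other 8 livers were closer to their own group. The first principal component held 27.6% of the variance and the second 18.4%. Exercised livers averaged -24.95 ± 30.4 on the first and control livers 24.95 ± 36.5 (SD, n = 5 each; exact permutation p = 0.0556, adjusted over 10 measures 0.278). On the second the means were 20.48 ± 32.9 and -20.48 ± 20.2 (exact permutation p = 0.0476, adjusted 0.278), so neither component alone separated the groups after adjustment. Control replicate 5 was the least similar to the rest, with a mean correlation of 0.918, and exercised replicate 2 was the least similar exercised liver, at 0.936. With both left out, edgeR called 0 genes at 4 livers per group, with 2894 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0544. On the same 8 livers limma-voom called 4 higher and 4 lower genes and DESeq2 called 523 and 541. With exercised replicate 2 alone left out, edgeR called 122 higher and 82 lower genes, and with control replicate 5 alone 162 and 137. No other pair of livers was left out. Whether this pair or the smaller groups took the calls was therefore not tested.

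**Figure D3:**
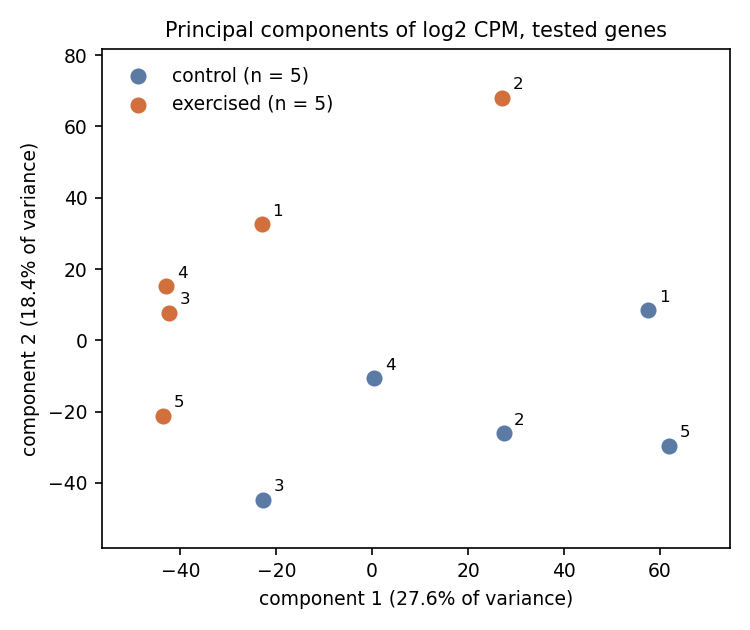
First and second principal component of log2 CPM over the 15621 tested genes, for 5 exercised and 5 control livers numbered by replicate; axes give the share of variance, 27.6% and 18.4%. Exercised replicate 2 lies on the side of the control livers on the first component, and control replicate 3 lies on that of the exercised livers.

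The deposited RPKM did not carry the same comparison as the counts. Of 199419 cells with counts above 0, 99.9995% equalled, within 0.0011 RPKM or 0.05% of the value, the count divided by gene length and by a library total that stepped through the 10 libraries from row to row. With the total of the column's own library and the same lengths, 12.9% did. The total of another library was used in 90% of all cells, and deposited values were 0.67 to 1.49 times those rebuilt with the library's own total. The factor depended on the row and the library. On log2(RPKM + 1), limma called 20 higher and 5 lower genes on the deposited values, and 402 and 81 on the rebuilt values. Of the 25 calls on the deposited values, 24 were also called on the counts, in the same direction. Of the 514 calls on the counts, 313 were called on the rebuilt values, which carry library totals without TMM factors.

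**Figure D4:**
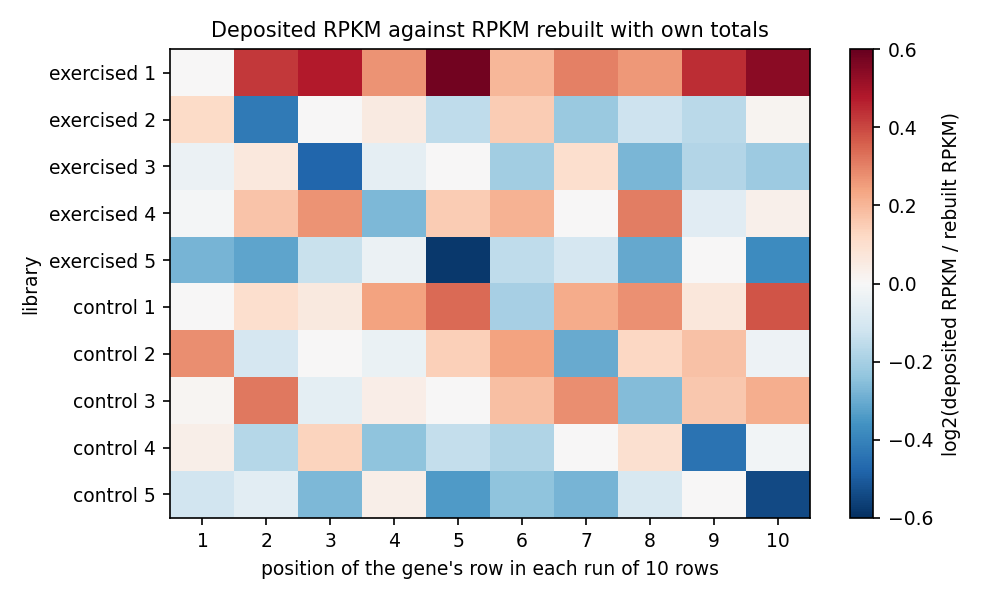
Deposited over rebuilt RPKM as log2 (colour) for each library (y axis) and each position of a gene's row within runs of 10 rows (x axis); red is too high and blue too low. The ratio lies between 0.67 and 1.49, and exercised replicate 1, the deepest library at 40089247 counts, was never too low.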

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

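In a group of 5 livers, a value was marked where its gap to the nearest other was over 0.71 of the group's range. Chance gives this in about 1 of 20 groups, and 28 groups of values were examined. The values were not independent. The share of the most abundant gene is part of that of the 100 most abundant, and components are computed from these same livers. The chance rate is therefore only a rough guide. Exercised replicate 3 had 4.604% of its counts in the most abundant gene, where the next exercised liver had 2.921%. It also had 52.8% of its counts in the 100 most abundant genes, where the next had 44.29%. On the third principal component, which held 14.6% of the variance, control replicate 4 lay at 61.17 and the next control liver at -0.937. Exercised replicate 3 was also highest of its group on that component, at 45.55, and the TMM factors of both libraries were the lowest of their groups, 0.896 and 0.718.

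The 514 genes past the threshold were weighed against 3 technical explanations; the tests for chance and gene length were set before their results were seen. A chance division of these livers was argued against: of 100 drawn splits of the 10 libraries into 5 and 5, out of 126 possible, 1 gave as many genes, the real split; the highest other gave 148 genes and 93 of the others gave 0. The split with 148 genes differed from the real one by exchanging exercised replicate 2 and control replicate 3. A trend on gene length was argued against as the whole source, since 96.9% of the calls remained with each library's trend removed. For scaling set by the most abundant genes, the test set beforehand, factors computed without the top 100, decided nothing: TMM trims the most abundant genes already, and the median change of all tested genes moved by only -0.016 on the log2 scale. Library totals and upper-quartile factors, weighed in its place after their results were seen, moved that median by 0.17 and -0.05. Through both scalings 65.6% of the calls remained, 250 higher and 87 lower genes. For the lower genes this argues against a shift of 0.17 as the whole source, since 1 factor per library shifts all genes alike. The higher genes were strained only by the shift of -0.05, under which 80.5% of them remained. That shift was too small to decide for them. Scaling does decide part of the calls: with library totals 87 of the 196 lower genes, or 44.4%, remained. The median change of the lower genes went from -1.18 to -1.01 on the log2 scale with the shift of all genes. The effect of exercise, and any difference in handling or housing between the groups, which the labels do not describe, stay open and were not tested.

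The loss of calls on the deposited RPKM was weighed with 2 tests chosen after the data were seen; for the fit on rebuilt RPKM, the bound was written before its result. Totals that cycle down the rows rebuilt 99.9995% of the cells, as division of a matrix by a vector of 10 totals would do in software that recycles vectors down columns. The log scale and the test were argued against as the source, since the same fit gave 19.3 times as many calls on RPKM rebuilt with each library's own total with a pseudocount of 1, and 5.96 times as many with 0.1. The error is a candidate explanation for weak or discordant results from any use of the RPKM table, and the counts are not touched by it.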

How the results depend on the processing

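Library totals without factors, rebuilt RPKM, removal of the length trend, factors without the top 100 genes, and leaving out both most dissimilar livers were chosen after seeing the data. The number of higher genes, 318, stayed within 1.5 times under RLE factors, upper-quartile factors, both filters, robust dispersions, limma-voom, library totals, rebuilt RPKM, the length correction and factors without the top 100 genes. The number of lower genes, 196, did so under the same settings except no filter (118), library totals (90) and rebuilt RPKM with pseudocounts of 1 (81) and 0.1 (82). DESeq2 called 925 higher and 668 lower genes, and limma-voom with sample weights 1391 and 1026. In the simulation DESeq2 made 32 false calls beside 94 right ones (15621 genes) and edgeR 0 beside 62 (15517). The simulated genes were independent and had edgeR's own dispersions, so the false calls of either test on the real data are not known from them. Library quality was not simulated, so sample weights were not judged. An adjusted p under 0.10 gave 712 and 517. The deposited RPKM gave 20 and 5 with a pseudocount of 1, and 66 and 19 with 0.1; values divided by other libraries' totals went into both. Leaving out 1 library gave 51 to 493 higher and 28 to 330 lower genes. The higher count moved by over 1.5 times without exercised replicate 1 (94), 2 (122) or 4 (59) and without control replicate 1 (73), 2 (51), 3 (172), 4 (493) or 5 (162). The lower count did so without exercised replicate 1 (41), 2 (82) or 4 (28) and without control replicate 1 (53), 2 (28), 3 (106) or 4 (330). Both most dissimilar livers left out gave 0 and 0, with 97.5% of the 514 calls at the same direction and an unadjusted p under 0.01. The cause of these shifts was not tested. Of the 514 calls, 15.4% to 87.9% were called again with 1 library left out, and at least 99.8% had the same direction with an unadjusted p under 0.01. None of the 514 changed direction under any of these settings where it was tested. The 514 were chosen on these same libraries, so their kept direction and small p are largely set by that choice. The 4 printed genes kept their calls except with both most dissimilar livers left out and, for Nfu_g_1_005339, on the deposited RPKM with a pseudocount of 1 (adjusted p = 0.0666). The difference in the share of the 10 most abundant genes, -2.39 percentage points, moved by over 1.5 times without exercised replicate 3 (-3.86) or control replicate 4 (-1.56). The log2 change of Nfu_g_1_010862 ranged over the alternatives from -2.85, in limma-voom with sample weights, to -1.20, on rebuilt RPKM with a pseudocount of 1. The planned gene list tests were not run, for want of gene names. At this depth and spread, with 5 livers per group, simulated 2-fold changes were called in 14.9% of genes; which of depth and spread limits the calls more was not tested.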

Other observations

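A single liver stood apart from the other 4 of its group, by over 0.71 of the range, in 6.74% of tested genes among control and 7.32% among exercised livers, where chance gives about 1 in 20. Control replicate 4 stood apart in 2.7% of genes, exercised replicate 3 in 2.54% and control replicate 5 in 2.3%, while control replicate 2 did so in 0.288%. Control replicate 5 had 9 genes at least 8-fold above all other livers, the most of any library.

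Genes in adjacent rows of the table, among those tested, tended to change together. Among the 514 called genes there were 33 adjacent pairs that changed in the same direction, 23 with both higher and 10 with both lower, where permutation of the calls within 20 abundance classes gave 8.96 on average and 22 at most (10000 permutations, one-sided p = 1e-04, the smallest they can give). Pairs of opposite direction numbered 5, against 8.01 on average. Pairs 2 rows apart numbered 7 and pairs 3 rows apart 8. The order of the rows is not explained in the sources used here; it may follow position along the genome, which was not tested. Of the tests on this pattern, the count of pairs with a nearly constant ratio and the comparison with distant pairs were chosen after the result was seen. An order unrelated to anything shared by neighbours was argued against, since the median correlation within groups of adjacent rows exceeded that of rows 1000 apart by 0.103 over all tested genes. A single gene counted in pieces, or reads wholly shared between neighbours, was argued against as the whole source for the pairs as a set: the ratio of their counts varied between livers with a median SD of 0.297 on the log2 scale beyond counting error (95% bootstrap interval 0.213 to 0.388). That SD was over 0.2 for 22 of the 33 pairs. Other values go with reads or pieces shared in part, and equally with neighbours regulated together: the median correlation within groups was 0.59 for these pairs, against 0.102 for all adjacent rows and 0.225 for called genes of one direction at least 100 rows apart, whose ratios had a median SD of 0.411. For the remaining pairs, 4 of them with an SD under 0.1, the explanation cannot be told apart from neighbours regulated together, since the gene models are not given. Reads shared in part between overlapping genes, duplicated genes and regulation of neighbours together stay open.

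A hypothesis that exercised livers resembled one another more than control livers did was tested and not borne out. The mean correlation within exercised livers exceeded that within control livers by 0.00921, and an exact permutation gave a two-sided p of 0.627.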
